A study of Homo sapiens and Mus musculus with 26 samples.

How the data were processed

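RNA was sequenced from HT29, an established human colorectal adenocarcinoma cell line, and from the colon of Apc(min/+) mice, which carry a mutant copy of the tumour suppressor Apc and develop intestinal adenomas. HT29 was grown as adherent cells or as colonospheres, that is, as spheres of tumour cells. Cells were kept in medium without serum as the control, or were given inhibitors of DGAT1 and DGAT2, the enzymes of the last step of triacylglycerol synthesis. Mice ate a regular or a high fat diet and received the inhibitors or a placebo by gavage. The labels name no compound, dose or duration. Per the labels, the RNA was treated with DNase and read as paired ends.

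The deposited tables hold TPM values per library and gene symbol. The mouse column names give that unit. The HT29 headers do not, and there it was read from the libraries' sums, which lie between 977014 and 998883 over all libraries. The tables also hold, per the file headers, a log2 fold change with its standard error, a p-value with its adjusted p-value, a test score that is the fold change over its standard error, and a mean signal over the libraries under the name that DESeq2 gives to the mean of counts divided by size factors. Per the submitters' processing notes, STAR 2.6.1d, kallisto 0.46.0, DESeq2 and the genome builds hg38 and mm10 were used, with no role or order given and no version of DESeq2. Read counts were not used here, because the tables hold TPM. TPM keeps no record of depth, so the depth of each library is unknown, and no counting interval or detection limit is given. A value listed at 0 is reported only as listed at 0, with no fold change.

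The adherent table listed 30390 entries, of which 26 had gene names turned into dates and were left out. The colonosphere table listed 26053 genes, and 54164 genes were listed for the mouse. Of the 26 samples, 25 libraries were used. The column of the second adherent inhibitor library holds no values, which left 4 of its group's 5 libraries. Column names tied the HT29 libraries to the samples, while the mouse columns could be tied only to their group, so mouse libraries are called a, b and c in column order. Mouse column names start with a number of 2 parts. The 3 columns of each high fat diet group share both parts, and 2 of the 3 have a further number added. The 6 regular diet columns differ in the second part, and controls b and c share the first, the meaning of which is not stated. Each high fat diet group could therefore be 1 animal, and the test between them would then compare 1 animal with 1 animal. The control libraries on the high fat diet appear in 2 tables, and 1 of them (c) differs between the tables for 21476 genes. The values of the comparison at hand were used in each case, and the differences between diets took that library from the table of the inhibitor comparison on the high fat diet.

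The tests planned for counts were replaced by those planned for normalised values. Log2(TPM + 1) was fitted per gene with limma 3.58.1 in R 4.3.3, with a trend in the variance, on the libraries of the groups compared and with group as the only term. A gene was tested if its mean reached 1 TPM in at least 1 group, and it was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on this scale, which understates the change of genes with low values. Differences between diets or culture forms were tested as interaction terms over 4 groups. For the culture forms, values were rescaled to TPM over the 24102 genes of both tables.

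Lists of genes fixed before the data were examined were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, where at least 3 members were measured. There were 23 human and 36 mouse lists. Those for both species covered triacylglycerol synthesis and lipid droplets, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and PPAR targets, the unfolded protein response, ATF4 targets, NRF2 targets, cell cycle, p53 targets and cell cycle inhibitors, FOXO targets, apoptosis, WNT targets, stem cells, absorptive colonocytes, goblet cells, enteroendocrine cells, hypoxia and glycolysis, epithelial-mesenchymal transition, inflammatory genes, interferon response, circadian clock and mitochondrially encoded transcripts. The human lists added small intestinal, gastric and hepatic markers. The mouse lists added adipocyte, smooth muscle, fibroblast, endothelial, T and NK cell, B and plasma cell, macrophage, neutrophil, MHC class II, enteric neuron, Paneth and small intestine, pancreatic acinar, squamous epithelium and sex-specific transcripts. Each camera test was repeated with a correlation estimated from the data. In that rerun the adjusted p also rose for some lists whose estimated correlation lay below 0.01. With an estimated correlation, camera also takes its p-value from the residual degrees of freedom, which were 4 to 9 here. A lost call therefore does not by itself show correlation among the genes of a list, and it says little about the list.

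The tests, comparisons, lists and rule for named genes were chosen before the data were examined. The rule named DGAT1 and DGAT2 (and Apc in mice), then the 10 highest and 10 lowest log2 changes among called genes with an assigned symbol, a mean of 1 TPM or more in a group and no overlap between the groups' libraries, and up to 4 members per list by p-value. Where fewer than 10 genes were called, the 5 of each direction with the smallest p-values are named as not passing. Some genes that the rule names are not reported here. Short RNAs (micro, small nucleolar, transfer and 7SL RNAs) and members of near-identical families (AKR1C, defensin, Scgb2b, immunoglobulin, globin and tubulin genes) are uncertain, because reads can be shared among copies or lost with short fragments. Gene coordinates were taken from GENCODE 44 on hg38 and GENCODE M21 on mm10, to which 22471 of 32315 human symbols and 53628 of 54164 mouse symbols were matched.

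On simulated data with known changes, the tests recovered 90% of genes changed by a log2 of 1 in adherent cells (15365 genes), 90% in colonospheres (14302 genes), 32% on the high fat diet (14457 genes), 16% on the regular diet (13363 genes) and 24% between diets (13466 genes). The interaction terms recovered 10% between diets (14835 genes) and 85% between culture forms (15037 genes). Alternatives were a pseudocount of 0.1, no filter on low values, an absolute log2 change of at least 1, and median-of-ratios scaling. Others were replicate number as a block, all 4 mouse or all 4 HT29 groups in 1 fit, and each library left out in turn. The rest were the authors' adjusted p-values, Xist as a covariate, and averaged high fat diet libraries. Nothing in the labels says that replicates are separate cultures or animals, so p-values measure only the spread between samples.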

Results

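The series addresses what the enzymes DGAT1 and DGAT2 contribute to colon cancer when obesity is present. RNA was profiled in HT29 cells grown adherent (3 control and 4 inhibitor libraries) or as colonospheres (3 and 3), and in Apc(min/+) mouse colon on a regular diet (3 and 3) or a high fat diet (3 and 3). Depth was unknown, since each library was given as TPM summing to between 977014 and 998883. DGAT1 lies at 144314584 to 144326910 on the minus strand of chromosome 8 in hg38, and DGAT2 at 75759512 to 75801535 on the plus strand of chromosome 11. In mm10, Dgat1 lies on chromosome 15 (76502015 to 76511953, minus strand), Dgat2 on chromosome 7 (99153658 to 99182719, minus strand) and Apc on chromosome 18 (34220924 to 34322552, plus strand).

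The mouse libraries differed in ways that the treatment and diet do not name. The Y-linked Ddx3y was found in all 3 control libraries on the high fat diet, whereas Xist, which is transcribed from an inactive X chromosome, was high in all 3 inhibitor libraries on that diet. Both regular diet groups held libraries with and without Xist (0, 33.2 and 40.3 TPM in controls a, b and c, and 0.0067, 0.0762 and 69.3 TPM in inhibitor libraries a, b and c). The median SD of a gene across libraries was 0.0716 on the log2 scale in the high fat diet inhibitor group, against 0.31 in its controls, 0.194 in the regular diet controls and 0.38 in the regular diet inhibitor group. In HT29 it was between 0.0947 and 0.158. Column names hold a number of 2 parts, and the 3 libraries of each high fat diet group, controls and inhibitors alike, shared both parts. On the regular diet no libraries shared both, while controls b and c shared the first part. Whether either high fat diet group holds more than 1 animal is therefore unknown. Correlations between libraries of the high fat diet inhibitor group were 0.982, against 0.919 to 0.949 in its controls.

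The first comparison asked what the inhibitors change in adherent HT29 cells. Of 27 interferon genes 26 rose, while 30 of 31 cell cycle and 24 of 25 cholesterol synthesis genes fell. Camera called these lists, each with adjusted p = 0.195 with an estimated correlation. ISG15, a ubiquitin-like protein induced by interferon, reached 2136 ± 311 TPM with inhibitors (SD, n = 4) against 375 ± 74.2 TPM in controls (SD, n = 3), a log2 change of 2.52. MKI67, a marker of dividing cells, stood at 10.04 ± 1.59 against 44.2 ± 4.27 TPM (log2 change -2.04), and FDPS, an enzyme of the mevalonate pathway, at 151 ± 18.0 against 458 ± 26.0 TPM (log2 change -1.60). PLIN2, which coats lipid droplets, rose from 12.8 ± 0.56 to 63.9 ± 15.6 TPM (log2 change 2.21). The targets rose too: DGAT1 stood at 58.1 ± 6.78 against 42.6 ± 1.83 TPM (log2 change 0.43, SE 0.0964, limma adjusted p = 0.00938). DGAT2 stood at 18.4 ± 1.81 against 12.3 ± 1.18 TPM (log2 change 0.54, SE 0.104, limma adjusted p = 0.00481).

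Of 15365 genes tested with limma, 5881 were called, 2440 higher and 3441 lower, and 1048 of them changed by a log2 of at least 1 (434 higher, 614 lower). With median-of-ratios scaling the split was 3037 higher and 2701 lower, and by the authors' deposited adjusted p it was 4042 and 3723. Among genes above 0 in both groups, the highest change was that of NUPR1, a stress-induced chromatin protein (251 ± 100.2 against 9.94 ± 2.53 TPM, log2 change 4.44, SE 0.351, adjusted p = 0.000121). It was followed by the steroid-reducing enzymes AKR1C2 (4.23) and AKR1C1 (4.12, 521 ± 159 against 28.2 ± 5.04 TPM), which share much of their sequence, and by the antiviral protein RSAD2 (4.10, 135 ± 38.3 against 7.01 ± 2.73 TPM). CEACAM5, a surface antigen of colon tumours, rose by 3.83, the ISG15-conjugating enzyme UBE2L6 by 3.81, HCG9 by 3.82 and OASL by 3.64. The short RNAs SNORD11 and MIR6891 were called higher and were listed at 0 in the controls. Among lower genes, AKAP12, a scaffold protein for kinase A, led (0.688 ± 0.12 against 24.4 ± 6.58 TPM, log2 change -3.88, SE 0.179, adjusted p = 6.67e-05). Next came the tubulin TUBA1A (-3.11, 8.43 ± 3.18 against 78.0 ± 9.77 TPM), and the guanylin precursor GUCA2A (-2.88). The nucleotide synthesis enzymes RRM2 (-2.72, 20.1 ± 4.68 against 136 ± 10.8 TPM) and TYMS (-2.59, 15.7 ± 1.47 against 100.2 ± 18.1 TPM), the thyroid hormone carrier TTR (-2.62) and the lectin REG4 (-2.54) were also among the 10 lowest. MIR5189 was called lower and was listed at 0 in the inhibitor libraries, and so were MIR548D1 and MIR1273D in 3 of 4 (8.36 and 4.50 TPM in the other).

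Camera called 15 of 23 lists, 7 higher and 8 lower. Of 27 interferon response genes, 26 rose and 0 fell, among them IFITM1 (3.22, 313 ± 72.9 against 32.1 ± 2.88 TPM), OAS1 (2.23) and the immunoproteasome subunit PSMB8 (1.88). The list's median log2 change was 2.49 (camera adjusted p = 8.61e-22, and adjusted p = 0.195 with an estimated correlation). Of 20 NRF2 targets, 17 rose and 1 fell, including the ferritin light chain FTL (2.04, 9159.8 ± 1886 against 2197 ± 49.6 TPM). Of 21 genes of the unfolded protein response 19 rose and 0 fell, such as SDF2L1 (1.19), CALR (0.80) and PDIA4 (0.76). By camera, the adjusted p was 1.66e-11 for NRF2 targets and 9.42e-11 for the unfolded protein response (each adjusted p = 0.195 with an estimated correlation). ATF4 targets had 7 of 22 members higher and 0 lower, including the amino acid transporter SLC3A2 (1.00), GDF15 (0.76) and VLDLR (0.45) (camera adjusted p = 0.00253, and adjusted p = 0.423 with an estimated correlation). The circadian clock list had 8 of 16 members higher and 1 lower, with DBP at 1.46 and PER1 at 0.58 (camera adjusted p = 0.00649, and adjusted p = 0.338 with an estimated correlation).

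**Figure D1:**
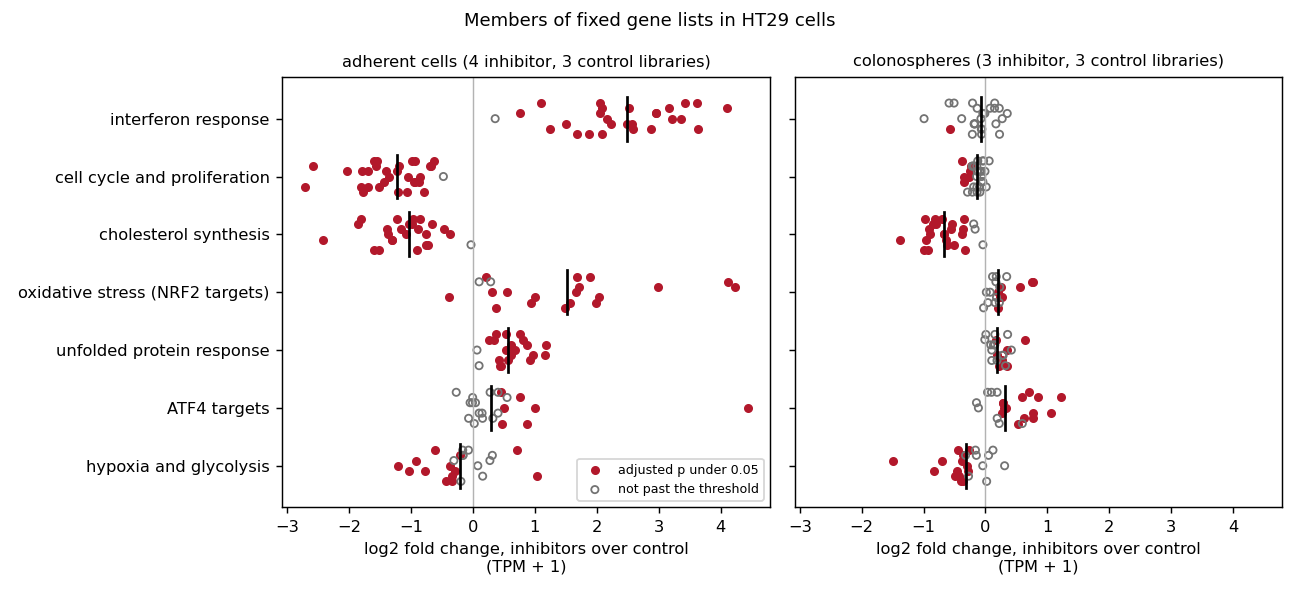
Log2 fold change (inhibitors over control, log2(TPM + 1) scale) of each measured gene of 7 lists in adherent HT29 cells and in colonospheres, where filled points passed the test (adjusted p under 0.05) and bars are list medians. Interferon genes had a median of 2.49 in adherent cells and -0.07 in colonospheres, and cholesterol synthesis genes had medians of -1.04 and -0.66.

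Lipid genes of adherent cells went several ways. Cholesterol synthesis had 24 of 25 genes lower and 0 higher, with HMGCS1 at -1.87 and CYP51A1 at -0.98 (median -1.04, camera adjusted p = 6.41e-13, and adjusted p = 0.195 with an estimated correlation). The triacylglycerol and lipid droplet list had 10 of 25 members higher and 2 lower, among them PLIN4 (1.47), BSCL2 (1.07) and the lipase LIPE (1.06). Of 26 genes of fatty acid oxidation and PPAR targets 10 rose and 3 fell, including PDK4 (1.94), ANGPTL4 (1.73), UCP2 (1.48) and ACADVL (0.63). Camera called these lists higher, with an adjusted p of 0.0246 and 0.0261 (each adjusted p = 0.195 with an estimated correlation). Fatty acid synthesis was not called (camera adjusted p = 0.0884), with 2 of 15 members higher and 7 lower: the acetate-activating enzyme ACSS2 stood at -1.40, ACLY at -0.77, SREBF1 at -0.69 and ME1 at 1.18.

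Cell cycle genes had 30 of 31 members lower and 0 higher, with FOXM1 at -1.80 (median -1.23, camera adjusted p = 1.97e-16, and adjusted p = 0.195 with an estimated correlation). The list of p53 targets and cell cycle inhibitors had 10 of 23 members lower and 3 higher, with BTG2 at -1.74, PLK2 at -1.20, SESN1 at -1.05 and CCNG1 at -0.55 (camera adjusted p = 0.0495, and adjusted p = 0.195 with an estimated correlation). FOXO targets had 8 of 15 members lower and 2 higher, with CCNG2 at -1.36, KLF6 at -1.32, FOXO1 at -0.57 and FBXO32 at -0.54 (camera adjusted p = 0.0322, and adjusted p = 0.338 with an estimated correlation). WNT targets had 12 of 19 members lower and 0 higher, with SOX4 at -1.88, NOTUM at -1.46, PROX1 at -1.30 and CD44 at -0.66 (camera adjusted p = 0.000147, and adjusted p = 0.27 with an estimated correlation). Of 14 stem cell markers 9 fell and 1 rose, with PROM1 at -1.04, CD24 at -0.85 and ALCAM at -0.83. Goblet cell markers had 10 of 12 members lower and 0 higher, with the transcription factor ATOH1 at -1.92, FCGBP at -1.67, TFF3 at -1.49 and the mucin MUC2 at -1.39. The camera adjusted p was 0.00503 for stem cell and 0.000147 for goblet cell markers (each adjusted p = 0.195 with an estimated correlation). Of 9 mitochondrially encoded transcripts 4 fell and 0 rose, such as MT-CO2 (-0.75) and MT-CYB (-0.73) (camera adjusted p = 0.0322, and adjusted p = 0.505 with an estimated correlation).

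In adherent cells, counts adjusted over the list alone were 0 higher and 31 lower for cell cycle, 18 and 1 for NRF2 targets, and 10 and 3 for triacylglycerol and lipid droplet genes. They were 11 and 4 for fatty acid oxidation, 3 and 11 for p53 targets and 2 and 9 for FOXO targets. WNT targets had 0 and 13 and mitochondrial transcripts 0 and 6, and the other called lists had the same counts as over all genes. Camera's adjusted p lay between 0.0667 and 0.982 for the 8 lists not called. Among these, inflammatory genes had 8 of 16 members higher and 4 lower (LCN2 at 2.18, ICAM1 at 1.20). Hypoxia and glycolysis had 2 of 23 higher and 11 lower (CA9 at -1.03, LDHA at -0.77), and the camera adjusted p was 0.0667 for each. Apoptosis (7 of 22 higher, 5 lower) and enteroendocrine markers (0 of 4 higher, 2 lower) had a camera adjusted p of 0.157 and 0.0884. Absorptive markers (3 of 15 higher, 5 lower, with CEACAM7 at 2.22 and CDHR5 at 1.56), epithelial-mesenchymal transition (1 of 8 higher, 1 lower) and small intestinal, gastric and hepatic markers (2 of 5 higher, 2 lower) had 0.982 each. Camera compares a list with all other genes, and for the small intestinal, gastric and hepatic markers its sign (higher) differed from that of their median and mean.

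The second comparison put the same question to HT29 colonospheres. The list of cholesterol synthesis (22 of 25 members lower) and that of hypoxia and glycolysis (14 of 23) were called lower, and that of ATF4 targets (14 of 22) higher. With an estimated correlation camera gave adjusted p = 0.0608, 0.166 and 0.164. ABCG1, a sterol exporter that LXR receptors induce, rose (25.4 ± 4.06 against 5.36 ± 0.54 TPM, SD, n = 3 each, log2 change 2.05, SE 0.127, limma adjusted p = 0.00066). ACSS2, which makes acetyl-CoA from acetate, fell from 88.9 ± 5.71 to 18.7 ± 2.13 TPM (log2 change -2.19, SE 0.091, limma adjusted p = 0.000235). The fatty acid carrier FABP1 fell from 127 ± 4.11 to 34.6 ± 3.17 TPM (log2 change -1.85). PLIN2 rose from 45.9 ± 1.94 to 108 ± 8.95 TPM (log2 change 1.21). DGAT1 (35.7 ± 2.53 against 37.1 ± 1.69 TPM, log2 change -0.06) and DGAT2 (17.0 ± 0.86 against 14.2 ± 1.42 TPM, log2 change 0.25) did not pass, with limma adjusted p = 0.664 and 0.136.

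Of 14302 genes tested with limma in colonospheres, 1157 were called, 674 higher and 483 lower, with 541 and 715 under median-of-ratios scaling and 1054 and 1162 in the authors' deposited table. A log2 change of at least 1 was reached by 57 (25 higher, 32 lower). Without 1 library the count was 1027 (control 1), 309 (control 2), 730 (control 3), 393 (inhibitors 1), 287 (inhibitors 2) or 335 (inhibitors 3). After ABCG1, the highest changes were those of the signal recognition particle RNAs RN7SL2 (1.78) and RN7SL1 (1.38), PDK4, which restrains pyruvate oxidation (1.51, 22.1 ± 3.58 against 7.10 ± 0.96 TPM) and RGCC (1.47). They were followed by MIR429 (1.28), DEPP1 (1.23) and the stress cytokine GDF15 (1.22, 237 ± 15.2 against 101 ± 1.54 TPM). SCARNA4 and SNORD97 were called higher and were listed at 0 in controls. The lowest included ACSS2, FABP1, the aldolase ALDOC (-1.50, 83.4 ± 11.1 against 237 ± 21.1 TPM), C6orf223 (-1.44), RARRES1 (-1.43) and the keratin KRT13 (-1.38), and MIR623 and MT-TG were listed at 0 with inhibitors. The mitochondrial transfer RNA MT-TQ, also called lower, was listed at 0 in 2 of 3 inhibitor libraries (7.23 TPM in the other).

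In colonospheres camera called 11 of 22 lists, 5 higher and 6 lower. Of 25 cholesterol synthesis genes 22 fell and 0 rose, with FDPS at -1.0 (216 ± 7.64 against 432 ± 16.3 TPM), EBP at -0.96, LSS at -0.93 and DHCR7 at -0.89 (median -0.66, camera adjusted p = 8.97e-29, and adjusted p = 0.0608 with an estimated correlation). Hypoxia and glycolysis had 14 of 23 genes lower and 0 higher, including carbonic anhydrase CA9 (-0.83), PGK1 (-0.45) and ENO1 (-0.37) (camera adjusted p = 3.48e-12, and adjusted p = 0.166 with an estimated correlation). ATF4 targets had 14 of 22 members higher and 0 lower, including the cystine transporter SLC7A11 (0.77), PPP1R15A (0.76) and the serine synthesis enzyme PSAT1 (0.52). NRF2 targets had 8 of 20 members higher and 0 lower, such as AKR1C1 (0.75), FTL (0.27) and FTH1 (0.20). Camera's adjusted p was 3.66e-10 for ATF4 and 6.21e-08 for NRF2 targets (each adjusted p = 0.164 with an estimated correlation). The unfolded protein response had 7 of 21 members higher and 0 lower, including HERPUD1 (0.63), DNAJB11 (0.36) and MANF (0.34) (camera adjusted p = 4.98e-07, and adjusted p = 0.111 with an estimated correlation).

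Cell cycle genes had 6 of 31 members lower and 0 higher in colonospheres, at small changes such as -0.35 for MCM2, -0.34 for MCM3, -0.27 for CDC20 and -0.26 for MKI67 (camera adjusted p = 3.82e-08, and adjusted p = 0.166 with an estimated correlation). WNT targets had 4 of 17 members lower and 0 higher, with the protease MMP7 at -0.82, EPHB3 at -0.69, CCND1 at -0.43 and MYC at -0.18. Apoptosis genes had 4 of 22 members higher and 0 lower: the BH3-only proteins BMF (1.12) and BBC3 (0.63) promote cell death, whereas XIAP (0.39) blocks caspases. Absorptive markers had 1 of 15 members higher (KRT20, 0.44) and 2 lower (EMP1 at -0.61, CEACAM1 at -0.54), and the list was called lower. By camera, the adjusted p was 0.00452 for WNT targets, 0.0109 for apoptosis and 0.0142 for absorptive markers (each adjusted p = 0.166 with an estimated correlation). FOXO targets had 3 of 15 members higher and 0 lower, with FBXO32 at 0.73, KLF6 at 0.56 and CCNG2 at 0.35, and goblet cell markers were called lower as a list with 0 of 12 members passing. The camera adjusted p was 0.014 for FOXO targets and 0.0226 for goblet cell markers (each adjusted p = 0.314 with an estimated correlation).

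In colonospheres, counts adjusted over the list alone were 0 higher and 24 lower for cholesterol synthesis and 0 and 17 for hypoxia. They were 16 and 1 for ATF4 targets, 14 and 0 for NRF2 targets, 0 and 9 for cell cycle and 10 and 0 for the unfolded protein response. WNT targets had 0 and 5 by this adjustment, and the counts were 6 and 0 for apoptosis, 4 and 1 for FOXO targets, 1 and 3 for absorptive markers and 0 and 0 for goblet cell markers. Camera's adjusted p lay between 0.0722 and 0.951 for the 11 lists not called. Under median-of-ratios scaling 2 of these were called higher, fatty acid oxidation and PPAR targets (camera adjusted p = 0.0431) and inflammatory genes (camera adjusted p = 0.0399). Fatty acid oxidation and PPAR targets had 8 of 27 members higher and 2 lower (CPT1A at 0.59, SLC25A20 at 0.50) at 0.0722, and inflammatory genes 3 of 15 higher and 1 lower (LCN2 at -0.45) at 0.0785. Interferon genes had 0 of 26 higher and 1 lower (IFI6 at -0.57) at 0.0969. The p53 targets had 5 of 23 higher and 0 lower (CDKN1A at 0.57, PHLDA3 at 0.55) at 0.125, and triacylglycerol genes 1 of 23 higher and 1 lower (LPIN1 at -0.92) at 0.219. Fatty acid synthesis had 1 of 14 higher (ELOVL7 at 0.58) and 3 lower (SCD at -0.65, ACLY at -0.48) at 0.514. The others were stem cell markers (0 of 14 higher, 1 lower), clock (4 of 16 higher, 0 lower), mitochondrial transcripts (1 of 9 higher, 0 lower), small intestinal markers (0 of 4 higher, 1 lower) and epithelial-mesenchymal transition (0 of 8 higher, 0 lower). In this order, camera adjusted p was 0.405, 0.222, 0.169, 0.248 and 0.951. Median, mean and test differed in sign for fatty acid synthesis and epithelial-mesenchymal transition. Only 2 enteroendocrine markers were measured, too few for a test.

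The responses of the culture forms were compared directly with an interaction term. Each form had its own controls, and the labels name no dose or duration. A difference between the forms therefore cannot be told apart from one in dose, duration or experiment. Of 15037 genes tested with limma 4616 differed, 2926 with a higher and 1690 with a lower log2 change in colonospheres, with 2134 and 2210 under median-of-ratios scaling, and 1030 differed by a log2 of at least 1. The changes of AKAP12 (difference 3.71), GUCA2A (3.09), the cell cycle regulator RGCC (3.00), TUBA1A (2.93), LINC00261 (2.71), RRM2 (2.58) and TTR (2.45) lay higher in colonospheres. MIR3605 and SCARNA4, also higher, were listed at 0 in the colonosphere controls. MIR548D1 lay higher and MT-TQ lower, with the values at 0 given above. Lower in colonospheres were the changes of NUPR1 (-4.56, SE 0.421, limma adjusted p = 1.47e-05), UBE2L6 (-4.34), IFITM1 (-4.22), PSMB9 (-4.22), RSAD2 (-4.04), IFIT1 (-3.94), MX2 (-3.76), IFI44L (-3.75) and OASL (-3.71). DGAT1 differed by -0.49 (limma adjusted p = 0.011), while the difference for DGAT2 was -0.30 (limma adjusted p = 0.135).

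Camera called 11 of 23 lists for the difference between culture forms. Interferon genes had 26 of 27 members with a lower change in colonospheres (median difference -2.22, camera adjusted p = 5.94e-27), and cell cycle genes had 29 of 31 with a higher change, such as TYMS at 2.39 (median 1.13, camera adjusted p = 1.93e-16). Both had adjusted p = 0.13 with an estimated correlation. NRF2 targets had 2 of 20 higher and 16 lower (AKR1C2 at -3.68, FTL at -1.77), and the unfolded protein response had 1 of 21 higher and 9 lower. Their camera adjusted p was 5.12e-11 and 7.24e-06 (each adjusted p = 0.23 with an estimated correlation). Cholesterol synthesis had 14 of 25 higher and 0 lower (camera adjusted p = 0.000606) and WNT targets 9 of 19 higher and 2 lower, with SOX4 at 2.00 (camera adjusted p = 0.0217), each with adjusted p = 0.437 with an estimated correlation. Lists with higher changes also included p53 targets (15 of 23 higher, 0 lower, camera adjusted p = 0.00374, and adjusted p = 0.124 with an estimated correlation). Mitochondrial transcripts had 5 of 9 higher and 0 lower (camera adjusted p = 0.0215, and adjusted p = 0.502 with an estimated correlation). FOXO targets (7 of 15 higher, 0 lower), goblet cell markers (6 of 12 higher, 0 lower) and stem cell markers (7 of 14 higher, 0 lower) had camera adjusted p of 0.0059, 0.01 and 0.0217 (each adjusted p = 0.294 with an estimated correlation). Adjusted over the list alone, the counts were 1 higher and 10 lower for the unfolded protein response, 16 and 0 for p53 targets, 7 and 1 for FOXO targets, 6 and 0 for mitochondrial transcripts, 11 and 2 for WNT targets, and otherwise as over all genes. The 12 lists not called had camera adjusted p from 0.0538 to 0.929, and inflammatory genes among them held LCN2 at -2.63. Median, mean and test differed in sign for ATF4 targets, apoptosis, absorptive, inflammatory and small intestinal lists, none of them called.

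Fold changes in the culture forms were weakly related across 13443 genes (Pearson's r = 0.0916, Spearman's rho = 0.123), where genes are not independent replicates. Genes called higher in both forms numbered 161 against 107 from independent lists, genes lower in both 217 against 110, and genes called in opposite directions 59 (77.2 from independent lists) and 143 (152). In both forms (adherent, then colonospheres) the inhibitors raised PDK4 (1.94, 1.51) and PLIN2 (2.21, 1.21) and lowered ACSS2 (-1.40, -2.19), FDPS (-1.60, -1.0), ACAT2 (-1.81, -0.97), LPIN1 (-1.43, -0.92), ALDOC (-0.92, -1.50) and the claudin CLDN2 (-2.0, -0.93). Opposite changes were called for RGCC (-1.53, 1.47) and the retinol receptor STRA6 (1.63, -1.09), among others.

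**Figure D2:**
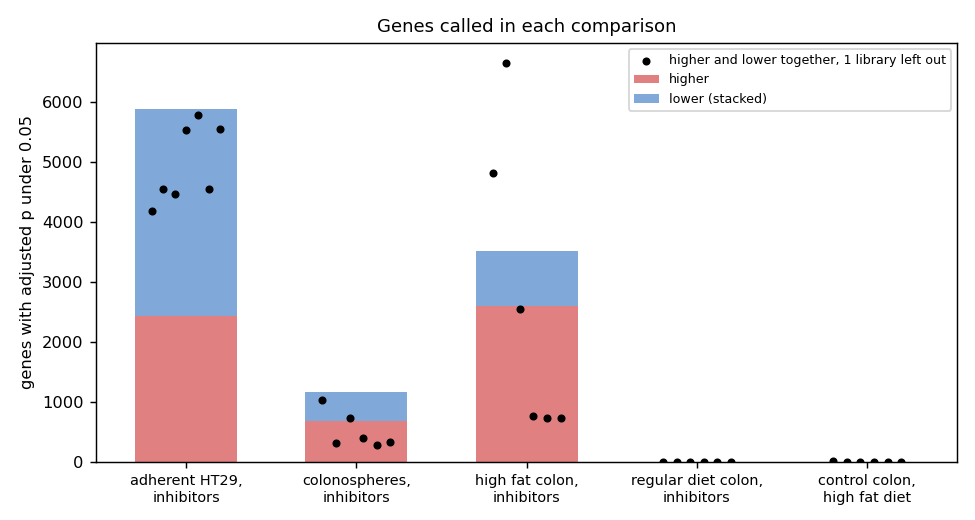
Genes called higher and lower (stacked bars, number of genes with limma adjusted p under 0.05) in 5 comparisons, with dots for the total when 1 library is left out. The bars stand at 5881 genes in adherent cells, 1157 in colonospheres, 3523 on the high fat diet, and 0 on the regular diet and between diets, and on the high fat diet the dots run from 723 to 6661.

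The comparison on the high fat diet asked what the inhibitors change in the Apc(min/+) colon on that diet. The lists of WNT targets, cell cycle genes and several kinds of immune genes were called higher in the inhibitor libraries, and those of the clock and of smooth muscle lower. With an estimated correlation camera called none of them (adjusted p from 0.381 to 0.525). Single genes of Paneth cells were higher, while the Paneth list was not called. The protease Mmp7 reached 1187 ± 30.4 TPM with inhibitors against 15.3 ± 22.9 TPM in controls (SD, n = 3 each, log2 change 7.40, SE 1.08, limma adjusted p = 0.00786). Lysozyme Lyz1, an antibacterial enzyme of Paneth cells, reached 3454 ± 25.7 against 35.4 ± 40.9 TPM (log2 change 7.19, SE 0.736, limma adjusted p = 0.00271). The WNT inhibitor Wif1 rose from 3.18 ± 4.07 to 98.9 ± 3.49 TPM (log2 change 5.01) and Axin2, a feedback target of WNT signalling, from 4.56 ± 0.94 to 16 ± 0.47 TPM (log2 change 1.63). Dgat1 (23.6 ± 0.83 against 25.8 ± 4.70 TPM, log2 change -0.11), Dgat2 (34.2 ± 0.95 against 32.0 ± 15.8 TPM, 0.23) and Apc (15.6 ± 1.01 against 19.5 ± 8.91 TPM, -0.22) did not pass, with limma adjusted p = 0.63, 0.666 and 0.587.

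Of 14457 genes tested with limma on the high fat diet 3523 were called, 2606 higher and 917 lower, with 1859 and 1450 under median-of-ratios scaling, and 1473 changed by a log2 of at least 1 (1193 higher, 280 lower). The authors' deposited table gives 2683 higher and 3071 lower. That scaling moved the median change of all genes from 0.151 to -0.0519, and those on the regular diet and between diets from 0.133 to 0.0237 and from 0.197 to 0.0101. The counts without 1 library were 4815, 6661 and 2545 (controls a, b, c) and 771, 723 and 723 (inhibitors a, b, c), and with the 3 inhibitor libraries averaged into 1 library limma called 0 genes. Such a fit takes its spread from the other group alone, and with the controls averaged instead it called 8281. Averaging leaves each fitted log2 change as it was by construction, so no sign can turn. With the inhibitor libraries averaged the median change was 0.143, which differs from 0.151 only through the genes that passed the filter. With Xist as a covariate, over all 4 mouse groups, 92 were called (78 higher, 14 lower) and 131 of the 3523 had the other sign. Xist hardly varied within each high fat diet group, so fits with this covariate take its slope almost wholly from the regular diet libraries. The groups also differed in sex transcripts: of 5 measured, Xist was higher (105 ± 3.37 against 0.101 ± 0.083 TPM, log2 change 6.59). Lower were Eif2s3y (-5.08), Ddx3y (-3.47), Kdm5d (-3.28) and Uty (-2.98), and the list as a whole was called lower (camera adjusted p = 0.000965, and adjusted p = 0.446 with an estimated correlation). Other leading genes were the angiogenin Ang4 (7.0, 1103 ± 10.8 against 27.2 ± 43.4 TPM), the phospholipase Pla2g2a (6.47, 604 ± 14.2 against 8.34 ± 9.23 TPM) and the lectin Itln1 (5.61, 187 ± 6.08 against 4.31 ± 5.36 TPM). The defensins Defa24 (5.66, 810 ± 22.6 against 20.3 ± 17.7 TPM), Defa3 (5.20) and Defa17 (4.28) were among them, as were the immunoglobulin segments Ighv9-3 (5.14) and Igkv12-41 (5.12). Besides Y-linked genes the lowest were the haemoglobin gene Hba-a1 (-3.47, 13.7 ± 1.70 against 167 ± 56.5 TPM), Igkv2-112 (-3.57), the troponin Tnni1 (-3.16), Ighv7-1 (-3.01), Naaladl1 (-2.98) and the iron transporter Slc11a2 (-2.95).

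**Figure D3:**
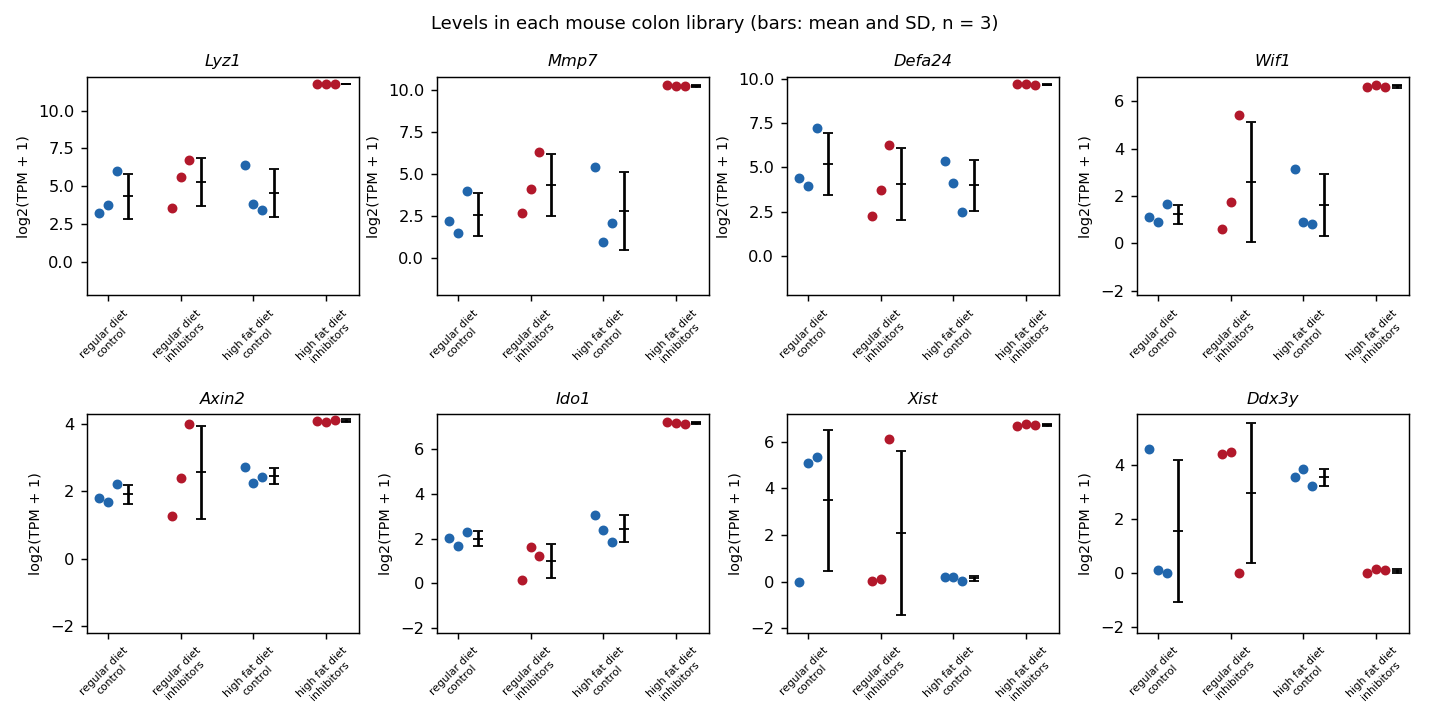
Levels of 8 genes in each mouse colon library, as log2(TPM + 1), in the 4 groups of diet and treatment, with the mean and SD of 3 libraries. Lyz1 was between 3424 and 3472 TPM in the high fat diet inhibitor libraries and at most 104 TPM in every other library, while Xist split the regular diet libraries.

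Camera called 17 of 35 lists on the high fat diet, 10 of them higher, and 15, 13 and 17 of these calls were kept without control library a, b or c (17 without any 1 inhibitor library). Under median-of-ratios scaling the unfolded protein response (lower) and ATF4 target, fibroblast, endothelial and neutrophil lists (higher) were called as well. WNT targets had 17 of 21 members higher and 0 lower, including the homeobox factor Prox1 (3.68, 21.6 ± 0.39 against 0.87 ± 0.83 TPM), Notum (3.46), Tcf7 (2.08) and Myc (1.22) (median 1.80, camera adjusted p = 4.8e-08, and adjusted p = 0.446 with an estimated correlation). Cell cycle genes had 20 of 31 members higher and 0 lower, including Ccnb1 (2.09, 40.1 ± 1.90 against 8.67 ± 1.08 TPM), Bub1 (1.93), Cdk1 (1.76) and Cenpf (1.42) (median 0.87, camera adjusted p = 7.11e-08, and adjusted p = 0.381 with an estimated correlation). Stem cell markers had 5 of 16 members higher and 0 lower, among them Lgr5 (2.34, 14.1 ± 0.29 against 2.08 ± 0.98 TPM), Smoc2 (1.94), Cd24a (1.79) and Bmi1 (1.18). The list of epithelial-mesenchymal transition had 7 of 16 members higher and 0 lower, including vimentin (Vim, 2.12, 199 ± 9.43 against 47.1 ± 16.3 TPM), Mmp2 (1.63), Mmp14 (1.29) and Snai2 (1.15). Camera's adjusted p was 0.0139 for stem cell markers and 0.0186 for that list (each adjusted p = 0.525 with an estimated correlation).

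Immune lists stood higher as well on the high fat diet. Inflammatory genes had 11 of 20 members higher and 1 lower, including Cxcl5 (3.27), Cxcl10 (2.36), Tnf (2.20) and Il6 (1.64) (camera adjusted p = 0.00185, and adjusted p = 0.446 with an estimated correlation). The interferon response had 13 of 23 members higher and 0 lower, including Ifitm3 (2.86, 300 ± 8.36 against 42.7 ± 18.5 TPM), Ifit2 (2.43) and Usp18 (2.22) (camera adjusted p = 0.00185, and adjusted p = 0.381 with an estimated correlation). MHC class II genes had 4 of 5 members higher and 0 lower, with H2-Ab1 at 2.87, H2-DMb1 at 2.58, Ciita at 1.18 and Cd74 at 1.01 (camera adjusted p = 0.00436, and adjusted p = 0.381 with an estimated correlation). T and NK cell markers had 3 of 5 members higher and 0 lower (Gzma 1.55, Gzmb 1.27, Cd3g 1.12). B and plasma cell markers had 4 of 6 higher and 0 lower (Iglv1 3.87, 640 ± 4.93 against 47.4 ± 22.5 TPM, Jchain 2.38, Igha 1.28). By camera, the adjusted p was 0.00975 and 0.0106 for these (each adjusted p = 0.446 with an estimated correlation). Macrophage markers had 4 of 9 members higher and 0 lower, including Lyz2 (1.62) and the complement gene C1qb (1.19) (camera adjusted p = 0.00589, and adjusted p = 0.525 with an estimated correlation).

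The circadian clock stood lower on the high fat diet, with 9 of 17 members lower and 0 higher, among them Nr1d1 (-1.74), Dbp (-1.12) and Npas2 (-1.03) (camera adjusted p = 0.000222, and adjusted p = 0.446 with an estimated correlation). The triacylglycerol list had 6 of 25 members lower and 1 higher, with the acyltransferase Agpat1 at -1.44, Cideb at -1.06 and Apob at -0.47 (camera adjusted p = 0.000338, and adjusted p = 0.488 with an estimated correlation). Fatty acid synthesis had 1 of 15 members lower (Thrsp at -1.32) and 0 higher, while Fasn, at -1.37, did not pass (camera adjusted p = 0.0139, and adjusted p = 0.381 with an estimated correlation). Fatty acid oxidation had 6 of 28 members lower and 1 higher, with Hadh at -0.90, Ehhadh at -0.62, Cpt2 at -0.58 and Slc25a20 at -0.54. Adipocyte markers had 2 of 8 members lower and 0 higher, Car3 (-2.53) and adiponectin (Adipoq, -2.08). Smooth muscle markers had 3 of 9 lower and 0 higher, Des (-1.35), Smtn (-1.01) and Tagln (-0.83). The camera adjusted p was 0.00129 for fatty acid oxidation, 0.00572 for adipocyte and 0.00129 for smooth muscle markers (each adjusted p = 0.525 with an estimated correlation).

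On the high fat diet, counts adjusted over the list alone were 18 higher and 0 lower for WNT targets, 21 and 0 for cell cycle, 9 and 0 for stem cells and 8 and 0 for epithelial-mesenchymal transition. They were 13 and 1 for inflammatory genes, 5 and 0 for T and NK cells, 5 and 0 for B and plasma cells, 9 and 0 for macrophages and 5 and 0 for MHC class II. Triacylglycerol genes had 1 and 7, fatty acid synthesis 0 and 0 and smooth muscle 0 and 5, and the other called lists had the same counts as over all genes. Of 10 Paneth and small intestine markers 5 were higher and 1 lower, and the list was not called (camera adjusted p = 0.342): the ileal bile acid carrier Fabp6 stood at -2.61 (6.47 ± 1.25 against 46.9 ± 21 TPM). The other 17 lists not called had camera adjusted p from 0.0508 to 0.803. They included ATF4 targets (9 of 21 higher, 1 lower, Psat1 at 2.13 and Phgdh at 1.80) and endothelial markers (3 of 8 higher, 0 lower, Pecam1 at 1.12). Fibroblast markers (3 of 10 higher, 0 lower) held Col3a1 at 1.81 and Col1a1 at 1.18. Neutrophil markers (2 of 5 higher, 0 lower) held Retnlg at 2.09 and Ltf at 1.99, and squamous epithelium markers (2 of 4 higher, 0 lower) Sprr1a at 1.73 and Krt13 at 1.33. NRF2 targets (6 of 16 higher, 1 lower) held Hmox1 at 0.78, p53 targets (5 of 20 higher, 1 lower) Plk2 at 2.12 and apoptosis (5 of 21 higher, 0 lower) Bmf at 1.16. Absorptive markers (0 of 21 higher, 4 lower) held Slc26a2 at -1.49, Cdx1 at -1.33 and Cdhr5 at -1.24. Of the others, enteroendocrine markers (0 of 10 higher, 1 lower) held Pyy at -1.23, and goblet cell markers (2 of 16 higher, 2 lower) Spink4 at 1.68 and Klk1 at -1.26. Cholesterol synthesis (2 of 25 higher, 1 lower) held Fdft1 at 0.61 and Dhcr7 at -1.0. The unfolded protein response, FOXO targets, hypoxia, mitochondrial transcripts and enteric neurons made up the rest, and pancreatic markers, with 2 measured, were not tested. Median, mean and test differed in sign for cholesterol synthesis, p53 targets, absorptive, goblet and enteric neuron lists. Median-of-ratios scaling turned the sign of the median for cholesterol synthesis, apoptosis, absorptive, goblet and enteric neuron lists.

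The comparison on the regular diet asked what the inhibitors change without the high fat diet. Limma called 0 of 13364 genes (smallest adjusted p = 0.199), 641 had an unadjusted p under 0.05, and the authors' deposited table gives 11 genes with an adjusted p under 0.05. Dgat1, Dgat2 and Apc had log2 changes of -0.34, -0.25 and 0.20. The genes with the smallest p-values, which did not pass, were on the higher side the cardiac troponin Tnnt2 (11.8 ± 4.45 against 3.06 ± 0.85 TPM, SD, n = 3 each, log2 change 1.62) and the repressor Tgif1 (36.1 ± 4.23 against 18.1 ± 2.31 TPM, 0.96). Next on that side were Dancr (0.97), Scarna17 (2.55) and Snora21, which was listed at 0 in controls. On the lower side they were the antibacterial lectin Reg3b (5.76 ± 4.63 against 27.4 ± 12.4 TPM, -2.19), Snurf (-2.55), Prap1 (-2.63), Igkv8-27 (-1.82) and Prss23 (-1.46).

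On the regular diet camera called 14 of 35 lists, 13 lower and 1 higher, with 0 members passing over all genes or adjusted over the list alone. Absorptive colonocyte markers had a median of -0.79, with guanylin (Guca2a) at -1.03 (1649 ± 771 against 3197 ± 786 TPM), Guca2b at -0.79, Tmigd1 at -2.64 and the water channel Aqp8 at -0.90 (camera adjusted p = 1.42e-08, and adjusted p = 0.783 with an estimated correlation). Goblet cell markers had a median of -0.45, with Retnlb at -2.98 and Zg16 at -0.54. Pancreatic acinar markers had a median of -1.93, where control library b held the highest values: trypsinogen Prss2 was at 0, 93.8 and 0.127 TPM in controls a, b and c and listed at 0 with inhibitors. Clps was at 32.1, 144 and 18.1 TPM in these controls and at 8.73, 24.4 and 23.2 TPM in inhibitor libraries a, b and c. For these lists the camera adjusted p was 0.000189 and 0.000156 (each adjusted p = 0.788 with an estimated correlation). Medians were -0.06 for triacylglycerol genes, -0.41 for adipocyte markers, -0.06 for ATF4 targets and -0.34 for enteric neurons (camera adjusted p = 0.00518, 0.00518, 0.0112 and 0.0125, and adjusted p = 0.788 with an estimated correlation for each). Fatty acid oxidation (-0.13) and enteroendocrine markers (-0.31) had camera adjusted p = 0.000189 and 0.000698, and adjusted p = 0.783 with an estimated correlation. Cell cycle (-0.20), cholesterol synthesis (-0.20), B and plasma cells (-0.28) and hypoxia (-0.07) had camera adjusted p = 0.000143, 0.00983, 0.0361 and 0.0381, and adjusted p = 0.907 with an estimated correlation. Inflammatory genes had a median of 0.58, with Lcn2 at 1.29, Cxcl2 at 0.88 and Birc3 at 0.59 (camera adjusted p = 0.0156, and adjusted p = 0.827 with an estimated correlation). The call of cholesterol synthesis turned to higher without inhibitor library a (camera adjusted p = 0.0011) and was lost without control library b (camera adjusted p = 0.168), and that of B and plasma cells was lost with median-of-ratios scaling, while WNT targets were then called higher (camera adjusted p = 0.00634). Of the 14 calls, 11, 10 and 12 were kept without control library a, b or c, and 8, 13 and 11 without inhibitor library a, b or c. The 21 lists not called had camera adjusted p from 0.0541 to 0.927, and median, mean and test differed in sign for fatty acid synthesis, NRF2 targets, apoptosis, interferon, smooth muscle and endothelial lists. Fewer than 3 T and NK cell markers were measured, too few for a test.

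The comparison of the control mice asked what the high fat diet itself changes. Limma called 0 of 13466 genes (smallest adjusted p = 0.0756), 1798 had an unadjusted p under 0.05, and the authors' deposited table gives 203, of which 66 are higher on the high fat diet. Without 1 library the count was 5, 0 or 1 (regular diet controls a, b, c) and 0, 1 or 3 (high fat diet controls a, b, c). Dgat1, Dgat2 and Apc had log2 changes of 0.12, 0.17 and 0.11. Genes with the smallest p-values, which did not pass, were Hyou1, a chaperone of the endoplasmic reticulum (29.3 ± 1.33 on the high fat against 12.1 ± 0.64 TPM on the regular diet, SD, n = 3 each, log2 change 1.21) and the glutamine transporter Slc38a1 (29.7 ± 1.71 against 9.74 ± 1.04 TPM, 1.52). Next were Cyp4f40 (1.54), Ighv6-3 (129 ± 79.0 against 1.83 ± 0.30 TPM, 5.34) and Igkv8-28 (4.72). On the lower side they were Ly6g6c (-2.44), Akr1b7 (-2.07), Ces2a (-1.72), the drug exporter Abcb1a (-2.09) and Gsta3 (-2.05).

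Between diets camera called 8 of 34 lists, 2 of them higher on the high fat diet. The unfolded protein response had a median of 0.43, with Calr at 0.93, Pdia4 at 0.85 and Creld2 at 0.82, and 8 of 21 members were higher adjusted over the list alone and 0 over all genes. Smooth muscle markers had a median of 1.16, with Smtn at 1.24 (the member higher adjusted over the list alone) and Des at 1.11. Absorptive markers had a median of -0.51, with 1 member lower adjusted over the list alone, the chloride exchanger Slc26a3 (-1.94, 308 ± 137 against 1102 ± 161 TPM), and Aqp8 at -1.55 (camera adjusted p = 3.41e-05, and adjusted p = 0.651 with an estimated correlation). Goblet cell markers had a median of -0.28 (Zg16 -1.17, Spink4 -1.16), pancreatic markers -1.84 (again with the highest Prss2 and Clps in regular diet control b), mitochondrial transcripts -0.19, and Paneth and small intestine markers -0.13. Cell cycle genes had a median of -0.09, with 2 members higher and 1 lower adjusted over the list alone. Camera's adjusted p was 0.000475 for the unfolded protein response, 0.00557 for smooth muscle, 0.000475 for goblet cells and 0.000777 for pancreatic markers. It was 0.0173 for mitochondrial transcripts, 0.0262 for Paneth and 0.0273 for cell cycle. All of these lists had an adjusted p = 0.899 with an estimated correlation, where camera was rerun. The calls of cell cycle, Paneth and pancreatic markers were lost with median-of-ratios scaling. Under it WNT targets, macrophage markers and epithelial-mesenchymal transition were called higher and NRF2 targets lower (camera adjusted p = 0.00992, 0.0129, 0.0331 and 0.022). Without 1 library the number of called lists was 14, 6 and 9 (regular diet controls a, b, c) or 11, 1 and 13 (high fat diet controls a, b, c), of which 8, 5 and 6 or 7, 1 and 5 were among the 8. The other 26 lists were not called, at camera adjusted p from 0.0658 to 0.825, and 15 of these had a positive median while the test, relative to all other genes, pointed lower (median change of all genes 0.197). T and NK cell and squamous epithelium markers, with 2 measured each, were not tested.

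Whether the inhibitors act differently on the 2 diets was tested with the interaction term. Of 14835 genes tested with limma 564 differed, 328 with a higher and 236 with a lower change on the high fat diet. Median-of-ratios scaling gave 975 (593 and 382). The larger side turned with a pseudocount of 0.1 (137 higher and 147 lower) and without high fat diet control b (635 and 787) or regular diet inhibitors a (556 and 1275). With Xist as a covariate 22 genes differed, with the high fat diet inhibitor libraries averaged to 1 library 38, and with both high fat diet groups averaged 0, where few libraries are left to give a spread. The tryptophan-degrading enzyme Ido1 had a difference of 5.71 (SE 0.538, limma adjusted p = 0.000486) and Lyz1 of 6.23 (limma adjusted p = 0.0331). Differences were also high for the secretoglobins Scgb2b17 (7.31), Scgb2b15 (7.14) and Scgb2b20 (6.17), Iglc1 (6.82), Igkv4-55 (5.28), Pla2g2a (5.53) and the defensins Defa24 (6.77) and Defa20 (6.44). They were low for Rnu12 (-4.33), the homeobox gene Hoxd10 (-4.27), Slc11a2 (-3.91), Igkv2-137 (-3.80), Igkv2-112 (-3.32), Ighv7-1 (-3.18), Ttr (-3.15), the diamine oxidase Aoc1 (-2.97), Cps1 (-2.93) and Trp53i11 (-2.87). Dgat1 (0.23), Dgat2 (0.48) and Apc (-0.42) were not called. Without 1 library the count was 1202, 1422 and 211 (high fat diet controls a, b, c), 132, 115 and 122 (high fat diet inhibitors), 150, 574 and 135 (regular diet controls) and 1831, 275 and 950 (regular diet inhibitors).

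Camera called 9 of 36 lists for the difference between diets. Higher changes on the high fat diet were found for cell cycle genes (3 of 31 higher, 0 lower, Ccnb1 at 2.55, Cdk1 at 2.17, Bub1 at 2.12, median 1.14, camera adjusted p = 2.79e-06) and WNT targets (1 of 21 higher, 0 lower, Lgr5 at 2.48, median 1.26, camera adjusted p = 0.00082), each with adjusted p = 0.772 with an estimated correlation. The same direction was found for stem cell markers (1 of 16 higher), interferon response (1 of 23 higher), T and NK cells (2 of 5 higher, Gzma at 1.93), MHC class II (1 of 5 higher, H2-DMb1 at 2.47) and endothelial markers (0 of 8 higher), none with a member lower. In this order, camera adjusted p = 0.0244, 0.00507, 0.000832, 0.00507 and 0.0459, and adjusted p = 0.772 with an estimated correlation for each. Smooth muscle markers had a median of -1.01 and 0 of 9 members passing (camera adjusted p = 0.0227, and adjusted p = 0.772 with an estimated correlation). The circadian clock had 2 of 17 members lower and 0 higher, Nr1d1 at -1.81 and Tef at -1.13 (camera adjusted p = 0.000208, and adjusted p = 0.654 with an estimated correlation). Adjusted over the list alone, the counts were 7 higher for cell cycle, 3 for WNT targets, 5 for stem cells, 2 for interferon, 4 for T and NK cells and 3 for MHC class II, and 8 lower for the clock and 2 for smooth muscle. Without 1 library the number of called lists was at most 16 (without regular diet control a, or without regular diet inhibitors c), and it was 14 without regular diet control c. Under median-of-ratios scaling, ATF4 targets and fibroblast, B and plasma cell and macrophage markers were called higher as well (camera adjusted p = 0.0346, 0.0455, 0.0286 and 0.0372). The 27 lists not called had camera adjusted p from 0.0539 to 0.998, and median, mean and test differed in sign for p53 targets, enteroendocrine markers and hypoxia.

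Whether the inhibitors move back what the diet moves was asked by correlating both sets of fold changes, which share the high fat diet controls. Across 13288 genes, which are not independent replicates, Pearson's r was -0.39 and Spearman's rho -0.371, against a mean r of -0.462 (-0.943 to 0.395) in 200 simulations with no effect, of which 131 were as low. The covariance was -0.139 against -0.0618 (-0.236 to 0.0322) in the simulations, a difference of -0.0767. Simulated libraries drew on residuals pooled over the 3 groups. The shared controls varied more (median SD 0.31) than the high fat diet inhibitor libraries (0.0716) and the regular diet controls (0.194). The simulated covariance follows the spread of the shared group and is likely too small in size, so the difference decides nothing. Among 18095 genes of the authors' deposited tables, 33 were called higher on the high fat diet and lower with inhibitors (11.2 from independent lists) and 57 lower and then higher (20.3). A further 13 were higher in both (9.79) and 8 lower in both (23.2). Independent lists leave out the shared controls, and part or all of the excess may come from them, of which 3 are too few to split.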

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

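The counts over other splits of the samples and the test of small intestinal genes were chosen after the results were seen.

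The inhibitor effect differed between culture forms for 4616 genes by the interaction term, and 1 of 100 drawn splits (the real grouping) gave as many genes, with 3827 in the highest of the others. The splits mix treatment in both forms, so at the 5% level they exclude chance only for a difference between inhibitor and control libraries in at least 1 form. For a difference between the forms they do not exclude it. The 3 other splits that kept the adherent groups gave a median of 3643 genes and the 6 that kept the colonosphere groups at most 9, so the count rests largely on the adherent groups. Of the 20 genes named for adherent cells by the size of their change, 18 were measured in both forms and 15 of them differed in effect between the forms. For the 20 named for colonospheres, 9 differed in effect. Genes named for an extreme change in 1 group are apt to differ from another, so these shares say little beside 4616 of all 15037 genes tested. On the mouse side, 564 genes differed in their inhibitor effect between diets, and 9 of the 20 genes named for the high fat diet were among the genes that differed (564 of all 14835 tested). That count of 564 was reached by 5 of 100 drawn splits, the real one included, so chance is not excluded. The highest of the others gave 1735 genes, and it kept the real groups on the high fat diet and mixed those on the regular diet. All 4 other splits that reached 564 were among the 10 that kept the high fat diet groups, while the 6 that kept only the regular diet groups gave at most 0 genes, so the count rests on the split within the high fat diet.

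Of 21 named genes tested for a library far from the rest among the 4 adherent inhibitor libraries, the short RNAs MIR548D1 and MIR1273D each had 1 library apart while the other 3 were listed at 0, with a gap over range of 1 for both, above Dixon's critical value. Chance alone singles out about 1 in 20 such groups.

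In adherent cells 1 of 35 splits (the real grouping) gave as many as 5881 genes and the highest of the others gave 671, so chance can be excluded. For colonospheres and for both diets the 6 libraries allow 10 splits, too few for a share under 0.05. The real split of the colonospheres gave 1157 genes and the highest other split 11, and the values were 3523 and 2 on the high fat diet and 0 and 6 on the regular diet (10 of 10 splits gave at least 0 genes). Between the control groups of the diets the real split gave 0 genes and the highest other split 142 (again 10 of 10 gave at least 0), in which libraries of both diets stood on each side, so these samples vary by more than the diet, and what sets them apart was not tested.

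The first pattern weighed is the set of 3523 genes called for the inhibitors on the high fat diet, where the column names share 1 full number within each group, controls included, so that 1 animal against 1 animal stays open. A candidate explanation for the small spread behind it is that the 3 inhibitor libraries are repeat libraries of 1 sample: immunoglobulin V genes, whose levels follow the B cell clones of an animal, had a median SD of 0.161 over 108 genes, 0.402 times that of the lower regular diet group, a ratio low enough for this explanation, although the spread over all genes was already known (the controls had 0.598, which is not low). More adenoma tissue in these libraries stays open. The median of 11 measured adenoma genes fixed before the test lay at percentile 99.94 of 10000 random lists. The median log2 change was 1.02 (SE 0.404), with 8 higher, 0 lower and 6 at 1 TPM or more in the high fat diet controls. Random lists ignore correlation among such genes, so the percentile decides nothing. The sex of the animals cannot be told apart from the treatment on this diet. The effects of 3518 called genes correlated with the change per unit of Xist in the regular diet libraries at 0.262 (64.7% of the same sign). Those of all tested genes did so at 0.118, and 5 genes were called for Xist over all 12 libraries. By the limits set, 0.262 was too high to discount sex and too low to assign the changes to it. Among the regular diet libraries, inhibitor library c held the highest Xist (69.3 TPM) and also the highest Wif1 (42.3 TPM) and Axin2 (15 TPM). The correlation may therefore come from other traits of that library, and it decides nothing about sex. An effect of the inhibitors themselves stays open beside these.

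The second pattern is the rise of Paneth cell genes such as Lyz1, Mmp7 and the defensins on the high fat diet. Small intestinal tissue rich in enterocytes is argued against in the inhibitor libraries, because enterocyte genes had a median log2 change of -1.02. Fabp6 stood at -2.61, Apoc3 at -1.40, Sis at -1.02, Apoa1 at -0.17 and Apoa4 at -0.12. The test was chosen after results were seen, and it does not cover small intestinal tissue with few enterocytes, which stays open. Paneth-type cells within adenomas also stay open, as the percentile of the adenoma genes decides nothing and none of these is in the Paneth list. With libraries that may repeat 1 sample, which the ratio of 0.402 does not decide, a trait of a single animal stays open as well, and so does the treatment.

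The third pattern is the fall of cholesterol synthesis genes in both HT29 forms. Excess sterol in the cells could lower them, and it would also raise the other targets of LXR receptors. In adherent cells the median of 8 such targets lay at percentile 41.3 of random lists (median log2 change -0.09, SE 0.446), with members called both ways, among them PLTP at 2.51, NR1H3 at 0.92, LPCAT3 at 0.35, APOC1 at -1.36 and SREBF1 at -0.69, so this test decides nothing there. In colonospheres it lay at percentile 92.2 (median 0.14, SE 0.176), with SMPDL3A at 0.84, MYLIP at 0.61 and APOC1 at -0.84, short of what sterol excess was set to require, while ABCG1 (2.05), RNF145 (1.18) and ABCA1 (1.10), known before the test, were higher (in adherent cells RNF145 at 0.83 was called, while ABCG1 at 0.52 and ABCA1 at -0.14 did not pass). The explanation stays open in both forms, as does a direct effect of the inhibitors, for which no test was run.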

How the results depend on the processing

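Median-of-ratios scaling, the authors' adjusted p-values, Xist as a covariate and averaged high fat diet libraries were chosen after the data were seen. DESeq2's and edgeR's tests and their normalisations were not run, because the tables hold TPM.

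Depth is unknown, so what it limits cannot be stated. Over 459 pairs of a named gene and a comparison, in 95 fits, 6174 values were recomputed: 5336 kept their side of the threshold, 760 kept direction and lost the call, 71 gained it and 7 reversed. Direction was compared only for genes called in either fit, so the 5336 can include uncalled genes whose sign turned. Calls required to exceed a log2 of 1 numbered 1048 in adherent cells, 57 in colonospheres, 1473 on the high fat diet and 1030 for the difference between culture forms, fewer by construction. No list was called with an estimated correlation, that is, 0 in each of the 7 comparisons. This rerun lost calls even where the estimated correlation lay below the preset 0.01. Fatty acid oxidation in adherent cells (-0.0309) went from a camera adjusted p of 0.0261 to 0.195. Fatty acid synthesis on the high fat diet (-0.0613) went from 0.0139 to 0.381. The rerun also takes its p-value from few residual degrees of freedom (4 to 9), which makes a call hard to reach. The lost calls thus cannot be put down to correlation among genes alone. The cause of the other shifts listed here was not tested unless stated.

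In adherent cells all other counts stayed within 1.5 times of 5881. Replicate number as a block gave 221 genes (131 higher, 90 lower) there and 468 (244 and 224) in colonospheres, with residual degrees of freedom lost by construction. Same-numbered libraries did not vary together (correlations -0.042 to 0.055), so the numbers do not pair the samples. For the mouse no paired analysis was possible, because its columns carry no replicate number of the labels.

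In colonospheres, 685 genes were called without a filter on low values, 2216 by the authors' deposited adjusted p, and 287 to 1027 with 1 library left out (fewer samples).

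On the high fat diet, 0 genes were called with the inhibitor libraries averaged to 1, 8281 (5265 higher, 3016 lower) with the controls averaged, 5754 (2683 and 3071) by the authors' deposited adjusted p, and 723 to 6661 with 1 library left out. All 4 mouse groups with Xist as a covariate called 92 (78 and 14), and the sign turned for 131 of the 3523 called genes, with named ones being Eif2s3y (1.87), Ddx3y (1.73), Kdm5d (0.71), Uty (1.17), Cxcl5 (-0.23), Igha (-0.071) and Cd74 (-0.81), where Y-linked genes turn because Xist carries their difference.

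On the regular diet, all 4 groups in 1 fit called 1 gene and the authors' deposited adjusted p 11. Leaving out 1 library left the count at 0, while the camera adjusted p of the cholesterol synthesis list ranged from 0.000236 to 0.168, with the sign turned without inhibitor library a (0.0011). Without that library 2871 of 13544 genes had an unadjusted limma p under 0.05, against 641 of 13364 with all libraries. Without any 1 of the others this number was 178 to 824. Between diets, all 4 groups in 1 fit called 25 (18 and 7), the authors' deposited adjusted p 203, and leaving out 1 library 0 to 5, with 1 to 14 lists called.

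The difference between diets stood at 284 genes (137 higher, 147 lower) with a pseudocount of 0.1, 975 with median-of-ratios scaling, 22 with Xist as a covariate, 38 with the high fat diet inhibitor libraries averaged, 168 with the controls averaged and 0 with both averaged. A group averaged to 1 library has no spread of its own, so the test takes it from the other groups. Averaging leaves the fitted log2 changes as they were by construction. With 1 library left out it was 115 to 1831 genes (556 higher and 1275 lower at the most) and 7 to 16 lists. For the difference between culture forms, all counts other than that above a log2 of 1 stayed within 1.5 times of 4616.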

Other observations

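Nothing in this part was planned before the data were examined except the lists and levels named in the report.

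Haemoglobin transcripts, which come from red blood cells, varied widely among the mouse libraries. Hbb-bs stood at 275 ± 4.73 TPM in the high fat diet inhibitor libraries against 1642 ± 296 TPM in their controls (SD, n = 3 each, log2 change -2.56), while it ran from 149 to 3270 TPM and Hba-a1 from 7.86 to 160 TPM within the regular diet controls. The antimicrobial goblet cell protein Retnlb had a log2 change of 6.88 on the high fat diet and did not pass (limma adjusted p = 0.0615), with 945, 1.32 and 5.41 TPM in controls a, b and c. The immunoglobulin heavy chain Igha stood at 131 ± 40.9 TPM in the high fat diet controls against 25.1 ± 3.82 TPM in the regular diet controls (SD, n = 3 each, log2 change 2.30), which did not pass either (limma adjusted p = 0.0756).

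The regular diet inhibitor libraries differed among themselves in genes that were high in all high fat diet inhibitor libraries. Libraries a, b and c held Wif1 at 0.515, 2.39 and 42.3 TPM, Axin2 at 1.42, 4.29 and 15 TPM, Mmp7 at 5.43, 16.2 and 79.1 TPM and Lyz1 at 10.99, 48 and 104 TPM. In the regular diet controls Wif1 lay between 0.858 and 2.16 TPM, Axin2 between 2.23 and 3.68, Mmp7 between 1.87 and 15.1 and Lyz1 between 8.48 and 65.0. Other such genes went another way: Defa24 reached 147 TPM in these controls against 75.8 TPM with inhibitors. Ido1 lay between 0.115 and 2.08 TPM with inhibitors and between 2.15 and 3.99 TPM in controls. Inhibitor library c was also the only library of its group with high Xist (69.3 TPM). Among the high fat diet controls, library a held Wif1 at 7.87 TPM against 0.889 and 0.77 TPM in b and c, and Mmp7 at 41.8 TPM against 0.931 and 3.21 TPM.

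Immunoglobulin V genes had a median SD across libraries of 0.598 in the high fat diet controls, 0.401 in the regular diet controls, 0.635 in the regular diet inhibitor group and 0.161 in the high fat diet inhibitor group. The mitochondrial transcript mt-Atp8 took 5.83% to 12.2% of TPM in the mouse libraries and was their most abundant transcript.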
